A study of Corynebacterium glutamicum R with 7 samples.

How the data were processed

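The data were 7 2-colour Agilent arrays of Corynebacterium glutamicum R, a soil bacterium of the actinobacteria. Per the labels, wild-type cells carried either the sigD overexpression plasmid (pCRC646, 4 arrays) or the empty vector (pCRB12iP, 3 arrays). Cultures grew at 33 °C in a nutrient-rich medium with glucose, and the inducer IPTG was added to 0.5 mM during exponential growth. Each array compared total RNA of a culture before IPTG with total RNA 15 min after it. The RNA was turned into cDNA and labelled indirectly with Cy3 or Cy5. The RNA after IPTG carried Cy5 on sigD replicates 1 and 2 and on vector replicate 3, and Cy3 on sigD replicates 3 and 4 and on vector replicates 1 and 2. The series design text speaks of 4 independent experiments. For the vector arrays nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

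Per the file headers, the scanner files hold the output of Agilent Feature Extraction 10.5.1.1. The submitters' processing notes name version 10.5.5.1. The deposited spot values used here are linear intensities, namely the median pixel intensity of each spot and of its local background in both channels, with no correction applied. Processed intensities of both channels, which per the file headers were background-subtracted and dye-normalized within each array, served in an alternative. The deposited LogRatio column is a log10 ratio of Cy5 over Cy3 per the file headers. It matched the log10 ratio of the processed intensities except on 110 to 343 spots per array, all of which were listed at 0. The authors' value table of the series holds 1 log2 ratio per probe and array, and how it was made is not given in the sources used here. Set against each array's own processed intensities, its columns correlated with log2 Cy5 over Cy3 with r of 0.948 to 0.999 and slopes of 0.909 to 0.997. Its column medians lay between -0.0033 and 0.0234. Scale, centring and direction of that table are therefore known from this comparison, and only the authors' method is not.

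Each array had 6864 spots, of which 308 were control spots (302 of them empty) and the others were 3278 probes with 2 spots each. No spot was saturated, and 0.061% to 1.60% of the probe spots of an array were marked as outliers by the scanner software and left out. Probe identifiers in the files are running numbers such as ID_763. The files do not pair them with gene names, accessions or sequences. The gene table at hand describes another strain of the species and shares no identifier with the probes, so 0 probes were matched to a gene. Results are therefore given per probe, and at most 2 identifiers that rose and 2 that fell are printed.

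Ratios were computed in R 4.3.3 with limma 3.58.1. The background was corrected with normexp (offset 50) on all spots, each array was normalized with loess with control spots at weight 0, and the log2 ratios of the 2 spots of a probe were averaged. The design written before the data were examined assumed mean spot intensities. The median intensities were used in their place because these are the spot intensities in the files. A probe was tested where it was well above background in at least 1 channel on at least 3 arrays, which left 3142 probes and removed 136. All 7 arrays entered 1 linear model with a dye term per probe and a before-after response for each plasmid, with the sign turned where the dyes were swapped. Moderated statistics came from lmFit and eBayes, with 4 residual and 4.02 prior degrees of freedom. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all 3142 probes, separately for each comparison, with a threshold of 0.05. The comparisons were the difference between the plasmids' responses (sigD minus vector), the response with the sigD plasmid and the response with the empty vector. Positive values mean more RNA after IPTG, or a larger rise with the sigD plasmid. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the tests along the probe numbers and for the plots.

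The rule for named features was fixed before the data were examined. It took the 14 probes higher and the 8 probes lower with the greatest difference among those past the threshold for which the arrays of the plasmids did not overlap, and the 6 higher and 6 lower of each before-after response with the same sign on every array. The 2 strongest of each direction of the difference are printed by identifier, and the others appear in ranges. The sigD probe itself, the gene lists and the promoter motif that were planned were not analysed here, because they need gene names or sequences.

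The fit was tested on simulated data, in 10 simulations of 3142 probes of which 200 were changed. The noise was normal, with each probe's fitted spread, and independent between probes and arrays. Day effects, differences in array quality and correlation between probes were left out. The rates below therefore hold where the model holds and may be too favourable for the real arrays. For the difference between plasmids, 80.2% of probes changed by 1.23-fold were recovered, 98.0% at 1.41-fold, 99.8% at 2-fold and 100% at 4-fold, with 4.5% false calls. The number of arrays limits the precision. Signals stood clear of the background for most probes. Per array, 94.1% to 96.2% of probes were well above background in the channel after IPTG and 92.5% to 94.6% in the channel before it.

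Scan days were read from the files and are called A to D here. Day A held sigD replicates 1 and 2, day B sigD replicate 3 and vector replicate 1, day C sigD replicate 4 and vector replicate 2, and day D vector replicate 3. Within days B and C the dyes ran the same way. In the files of sigD replicate 4 and vector replicate 2, a header field carries another name than the label, that of a vector array in the first and that of an array outside the 7 in the second. The log2 response of ID_763 was 6.72 on sigD replicate 4 and 0.64 on vector replicate 2. Across probes, sigD replicate 4 correlated with sigD replicate 3 with r = 0.97. Its r with the vector arrays was 0.60 to 0.77. Vector replicate 2 correlated with vector replicate 1 with r = 0.88 and with vector replicate 3, of opposite dyes, with r = 0.66. Its r with the sigD arrays was 0.50 to 0.77. With the fitted dye term removed, in a fit that uses the labels, the values for vector replicate 2 became 0.83, 0.84 and 0.68 to 0.76. Each file was taken for the sample under which it was deposited, and the replicate and scan day assignments, the values within day C and those with single arrays left out rest on that. The scanner software used a second protocol for vector replicates 2 and 3. Alternatives planned before the data were examined covered the background correction, the processed intensities, the series value table, normalization within and between arrays, the dye term, the filter, array weights, scan day and replicate number as blocks, a size threshold, separate fits per plasmid, and leaving out each array in turn. Added after seeing the data were fits on the upper or lower spot copy alone, a fit without the sigD arrays of day A, and a fit without the 2 arrays whose headers name another sample. Scan day as a block was planned, and whether it was fixed or random was settled once the days were known.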

Results

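Transcript levels of wild-type C. glutamicum R were measured on 7 2-colour arrays, each setting RNA taken 15 min after IPTG against RNA taken before it. On 4 arrays the cells carried a plasmid from which IPTG induces sigD, and on 3 the empty vector. The gene sigD encodes a sigma factor of the extracytoplasmic function family, a subunit that directs RNA polymerase to particular promoters. The series design names the comparison before and after sigD overexpression, and the vector arrays carry what IPTG, further growth and handling did without the insert. Median signals above background ranged from 1456 to 3411 after IPTG and from 1445 to 2938 before it, over local backgrounds of 117 to 215. The SD of a single spot, estimated from the differences between the 2 spots of a probe, was 0.06 to 0.10 on the log2 scale. Across probes, which are not independent replicates, after/before log2 ratios of arrays of the same plasmid correlated with r of 0.66 to 0.97, and those of different plasmids with r of 0.48 to 0.77. Before the signs were turned, arrays of opposite dye orientation correlated with r of -0.86 to -0.48, so their relative orientations run as in the labels. These correlations would be the same with every label reversed, so the direction itself rests on the labels.

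The difference between the plasmids asks which transcripts responded to IPTG otherwise with sigD on the plasmid than without it. The strongest was the probe ID_763, whose RNA rose 116-fold with the sigD plasmid and 1.49-fold with the empty vector, a 77.9-fold difference (95% confidence interval 68.3 to 88.7). ID_2154 came next among the probes, with a rise of 17.9-fold with the sigD plasmid, 1.56-fold with the vector and an 11.5-fold difference (interval 10.1 to 13.1). In all, 33 probes rose at least 2-fold more with the sigD plasmid, 13 of them by more than 4-fold and 5 by more than 8-fold. Only 2 probes, ID_1275 and ID_1015, were at least 2-fold lower. Which genes these probes stand for is not given in the sources used here, and whether ID_763 is the probe for sigD was not analysed.

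For ID_763 the mean log2 response was 6.86 ± 0.10 (SD, n = 4) with the sigD plasmid and 0.57 ± 0.13 (SD, n = 3) with the vector. The difference of 6.28 had a standard error of 0.08 and an adjusted p of 2.69e-09 in the limma fit. The sigD arrays lay between 6.72 and 6.94 for ID_763, and the vector arrays between 0.42 and 0.66. For ID_2154 the responses were 4.16 ± 0.11 (SD, n = 4) and 0.64 ± 0.13 (SD, n = 3), with a difference of 3.52, a standard error of 0.08 and an adjusted p of 3.68e-08. ID_1275 fell 3.13-fold with the sigD plasmid, a log2 response of -1.65 ± 0.10 (SD, n = 4), against -0.28 ± 0.12 (SD, n = 3) with the vector. Its difference of -1.37 had a standard error of 0.08, a 95% confidence interval of -1.55 to -1.19 and an adjusted p of 1.18e-05. ID_1015 fell 2.53-fold with the sigD plasmid, a log2 response of -1.34 ± 0.15 (SD, n = 4), while the vector response of -0.11 ± 0.12 (SD, n = 3) did not pass the test (adjusted p 0.241). Its difference was -1.23 (standard error 0.10, adjusted p 0.000105).

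**Figure D1:**
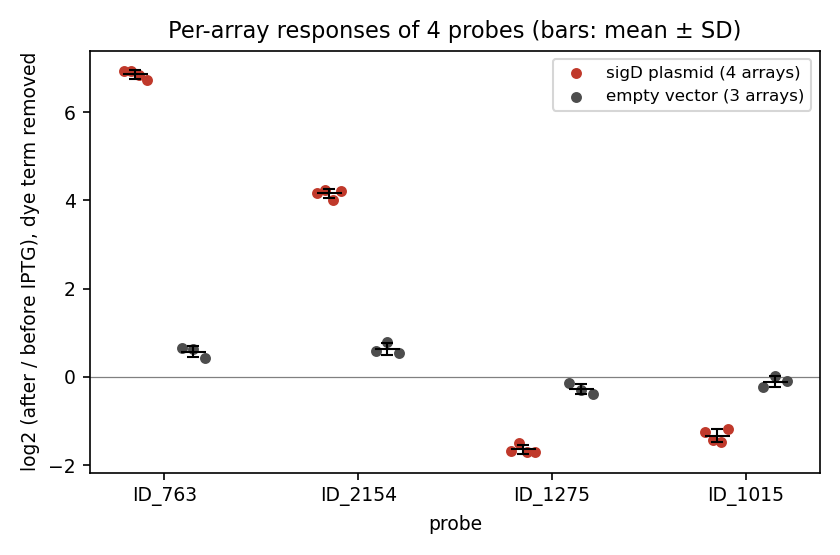
Responses to IPTG of the 4 probes named in the text, as log2 of RNA after over before IPTG with the dye term removed. Each point is 1 array (4 with the sigD plasmid, 3 with the empty vector) and the bars give mean and SD. For each of the 4 probes all sigD arrays lay on one side of all vector arrays, which the naming rule required.

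The 14 probes that the naming rule took as highest differed by 1.92 to 6.28 on the log2 scale, which is 3.79-fold to 77.9-fold, with adjusted p of at most 0.00148. With the vector these 14 probes had responses of 0.02 to 0.87. The 8 probes it took as lowest differed by -1.37 to -0.67, with adjusted p of at most 0.00275. Some of these 8 rose with the vector, by up to 1.26, and less with the sigD plasmid. Among the 33 probes at least 2-fold higher, the median log2 response was 2.20 with the sigD plasmid and 0.25 with the vector. Of the 33, 22 also rose with the vector and 11 did not pass the test there. Every sigD array lay above every vector array for all 33, which largely follows from their choice on the same arrays.

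At an adjusted p of 0.05 without a size limit, 201 of 3142 probes were higher and 211 lower, 13.1% of those tested, and 982 had an unadjusted p under 0.05. Most of these differences were small, with a median size of 0.29 on the log2 scale. Among the 201 higher probes, 74 rose with the sigD plasmid and did not pass the test with the vector, and 93 rose with both and more with sigD. A further 8 rose with sigD and fell with the vector, 24 fell with the vector and did not pass the test with sigD, and 2 fell with both, less so with sigD. Of the 211 lower probes, 52 fell with the sigD plasmid and did not pass the test with the vector, 81 fell with both and more with sigD, and 21 fell with sigD and rose with the vector. The remaining ones rose with the vector, of which 30 also rose with sigD to a smaller extent and 27 did not pass the test there. For every probe of the 201 and the 211 the arrays of the plasmids did not overlap. This is largely fixed by the calling, which used the same arrays. Among all tested probes 35.9% showed no overlap in either direction. Chance gives 5.71% for 4 against 3 exchangeable arrays. These arrays differ in scan day, and a dye term fitted on the same arrays was removed from the values. The latter can raise the share, so 5.71% is only a rough mark.

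**Figure D2:**
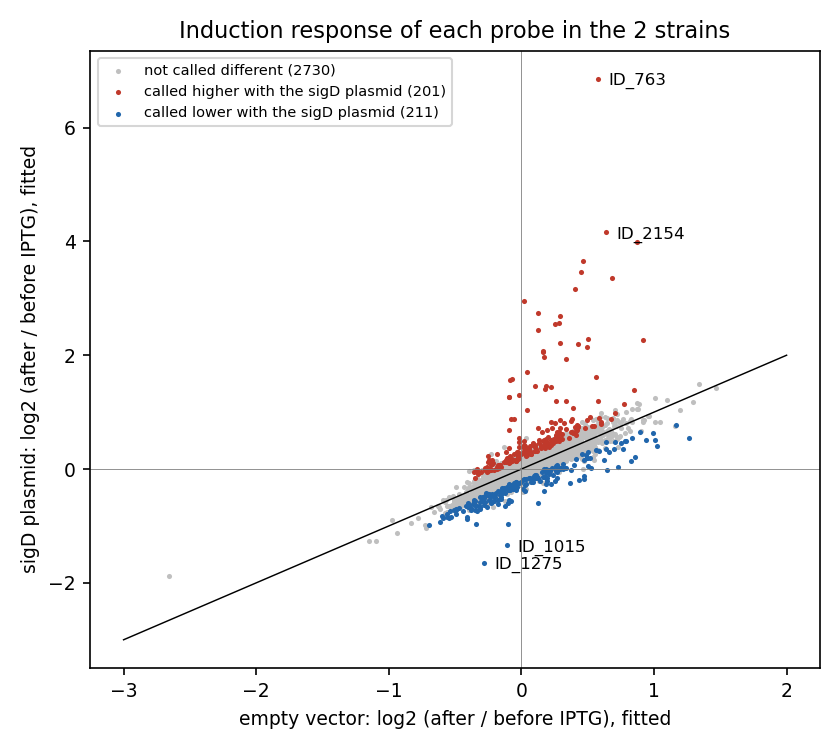
Response of each of the 3142 tested probes to IPTG with the empty vector (x axis) and with the sigD plasmid (y axis), both as fitted log2 of RNA after over before IPTG; the diagonal marks equal responses. Red points are the 201 probes called higher and blue points the 211 called lower with the sigD plasmid. The 4 named probes carry their identifiers. The 33 probes at least 2-fold higher with the sigD plasmid than with the vector stand above the diagonal, at vector responses under 1.

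Scan days B and C each held 1 array of either plasmid with the same dyes, so the difference could be read within a day. Within day B, 36 probes were at least 2-fold higher and 2 lower, and within day C 33 and 5. On each of these days all 33 higher and both lower probes of the full comparison were among them. These probes, with the named ones among them, were chosen for their size in a fit that includes the arrays of days B and C. Their recovery within a day is therefore largely fixed by that choice and is not an independent test. The log2 difference of ID_763 was 6.17 on day B and 6.09 on day C, and that of ID_2154 was 3.42 on both days. ID_1275 differed by -1.54 and -1.41, and ID_1015 by -1.25 and -1.19. With scan day as a fixed block, where the difference rests on the 4 arrays of these days, 59 probes were called higher and 27 lower, 34 and 2 of them at least 2-fold. This block takes up the dye term, since no day held both dye orientations. With scan day as a random block beside the dye term, 203 were called higher and 211 lower. Under the fixed block the log2 differences were 6.13 for ID_763, 3.42 for ID_2154, -1.47 for ID_1275 and -1.22 for ID_1015, with adjusted p of 1.88e-07, 3.11e-06, 0.000215 and 0.000534.

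The counts without a size limit depended on single arrays. They ranged from 66 higher and 40 lower without vector replicate 3 to 184 and 203 without sigD replicate 2, and without sigD replicate 1, 3 or 4 or vector replicate 1 they were 113 and 110, 102 and 83, 75 and 51, and 121 and 84. Without both arrays of day C, whose file headers carry the name of another sample, 95 and 76 probes were called, and without the dye term 74 and 58. The count of probes at least 2-fold different stayed at 32 to 37 higher and 2 lower over 25 alternatives, which shared 33 to 35 of the 35 probes with the full comparison.

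The comparison within the sigD plasmid asks how RNA levels changed between the sample before IPTG and the one 15 min later. Large changes were mostly rises, with 52 probes at least 2-fold higher and 7 at least 2-fold lower. The 6 strongest rises of the naming rule were 10.2-fold to 116-fold, and its 6 strongest falls 2.17-fold to 3.66-fold. Without a size limit 1109 probes were higher and 1097 lower, 70.2% of those tested, most by little, with a median size of 0.28 on the log2 scale. ID_763 and ID_2154 rose on 4 of 4 arrays, with adjusted p of 3.99e-11 and 3.41e-10. ID_1275 and ID_1015 fell on 4 of 4 arrays, with adjusted p of 8.41e-08 and 1.13e-06. Of the 52 large rises, 40 also rose with the vector, 6 of them at least 2-fold there, and 33 were at least 2-fold different between the plasmids. Of the 7 large falls, 6 also fell with the vector and 2 differed between the plasmids.

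The empty vector shows what followed IPTG without the insert. Large changes were few, with 13 probes at least 2-fold higher and 3 at least 2-fold lower. The 6 strongest rises were 2.24-fold to 2.77-fold and the 6 strongest falls 1.78-fold to 6.32-fold. The deepest fall belonged to a single probe that was also the deepest fall with the sigD plasmid (log2 -2.66 and -1.87), and its difference between plasmids did not pass the test. Without a size limit 919 probes were higher and 873 lower, 57.0% of those tested, with a median size of 0.25 on the log2 scale. ID_763 rose by 0.57 with the vector (adjusted p 0.00018) and ID_2154 by 0.64 (adjusted p 0.000127), each on 3 of 3 arrays. ID_1275 fell by 0.28 with an adjusted p of 0.00444, which became 0.0945 without vector replicate 3 at a log2 response of -0.17. All 13 large rises with the vector also rose with the sigD plasmid, with a median log2 response of 1.16 with the vector and 0.83 with sigD. They were chosen for their vector response, which by itself favours the higher median there. Of the 13, 4 differed between the plasmids, 0 of them by at least 2-fold.

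The responses in the strains carrying the 2 plasmids ran largely in parallel. With each plasmid fitted alone, their log2 responses correlated across probes with Pearson's r of 0.72 and Spearman's rho of 0.84. Probes that passed the test in both numbered 1562, of which 1533 (98.1%) moved the same way, 791 up and 742 down. Lists drawn independently would share 324 and 305. The other 29 of the 1562 moved in opposite directions. For all 29 the difference itself passed the test, which is nearly fixed by this choice of probes. Of the 1792 probes called with the vector, 1700 (94.9%) had the same sign with the sigD plasmid.

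**Figure D3:**
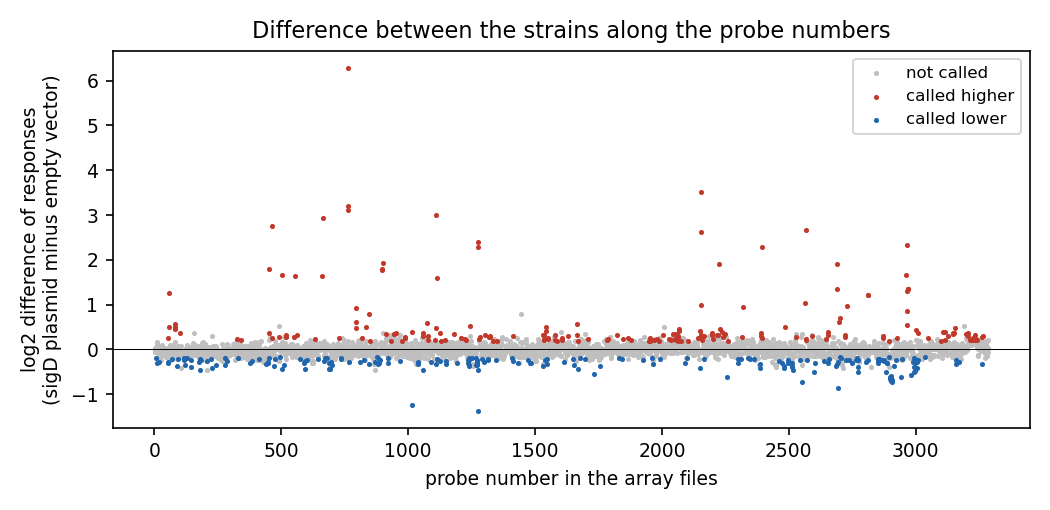
Difference between the plasmids in the response to IPTG (log2, sigD minus vector) of each tested probe along the probe number in the array files. Red points are the 201 probes called higher and blue points the 211 called lower, and several of the rises above 1 lie in small groups of neighbouring numbers.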

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

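The tests of explanations and the count of splits in this part were chosen after the results were seen, except the test of RNA of the strongest riser binding to other probes. The differences between the plasmids drew attention because the difference itself was tested. They were 6.28 on the log2 scale for ID_763, 3.52 for ID_2154, -1.37 for ID_1275 and -1.23 for ID_1015. For the count of called probes, the arrays were also split in other ways into 4 and 3. Of 34 splits that could be fitted, 1, the real one, gave as many as 412 probes, and the highest of the others gave 0. With all 7 arrays taken as exchangeable, this argues against chance in how they were grouped, at the smallest share that 34 splits can give. The arrays differ in dye and scan day, so they are not strictly exchangeable. Only 14 of the splits keep the arrays of day A together, as the real one does, and these are too few for a share under 0.05; the highest of the others among them also gave 0. The split that follows the dyes could not be fitted.

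A set of 29 probes moved in opposite directions with the plasmids. That their difference passed the test as well is nearly fixed by this choice of probes and adds nothing to it. They were 8 probes that rose with sigD and fell with the vector and 21 that did the reverse. Their responses were small, with class medians of 0.15 and -0.24 for the 8, and -0.16 and 0.18 for the 21, for sigD and vector in this order. No explanation was tested for them.

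Differences of at least 2-fold were mostly rises, 33 against 2, while the probes called at any size were 201 higher and 211 lower. In 4 fits with median centring, no background subtraction, processed intensities or the series value table, the rises were at least 16.5 times the falls. This argues against the choice of normalization among these settings as the whole cause. All 4 still normalize or centre the ratios within each array, so what centring itself does to the balance was not tested. Signals near background are argued against too, since 0 of the 33 probes failed to be well above background before IPTG on any sigD array. RNA of the strongest riser binding to other probes could also add rises and stays open, because the scanner files hold 0 columns of probe sequence. The overexpressed sigD, which the design names, may account for the rises, and this is left as a hypothesis.

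The sigD arrays formed 2 pairs, replicates 1 and 2 against 3 and 4, that differ in dye and in scan day. A gene-specific dye bias is consistent with the dye effect estimated from the sigD arrays and that from the vector arrays, which correlated across 3138 probes with r = 0.64. Scan day or culture day instead of dye cannot be told apart from it, because no scan day held more than 1 dye orientation and the days B and C enter both estimates. No biological explanation was tested for this pattern.

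Among the sigD arrays, replicate 1 lay apart in the share of probes well above background after IPTG. It had 96.0%, the other arrays of the group 94.1% to 94.3%, and its gap over the range was 0.857. This was 1 of 13 such tests, of which chance marks about 5%.

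The array also carries 3 control probes that the comparisons do not use. On 6 of 7 arrays 1 of them lay above the 99th percentile of the empty spots in both channels. Another lay above that level on 7 of 7 arrays. The remaining one lay above it on 0 arrays.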

How the results depend on the processing

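The fits on 1 spot copy, the one without the sigD arrays of day A and the one without the 2 arrays whose headers name another sample were chosen after seeing the data. Under 25 alternatives no called value of a named probe changed sign. The vector response of ID_1015, which passes the test in none of them, was -0.11 and became 0.01 under the replicate block without dye term. The log2 difference ranged from 5.72 to 6.37 for ID_763, 3.15 to 3.60 for ID_2154, -1.47 to -1.20 for ID_1275 and -1.35 to -1.11 for ID_1015, with adjusted p of at most 0.0171, and each stayed past the threshold. The vector response of ID_1275 missed it under the replicate block without dye term (-0.36, adjusted p 0.0521) and without vector replicate 3 (-0.17, adjusted p 0.0945), within adjusted p of 0.00157 to 0.0945 over all alternatives.

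Counts of the difference moved under several settings. Against 201 higher and 211 lower, they were 74 and 58 with no dye term, 59 and 27 with scan day as a fixed block without a separate dye term (203 and 211 with it as a random block beside the dye term), 63 and 38 without the sigD arrays of day A, 95 and 76 without the 2 arrays whose headers name another sample, and 33 and 2 at 2-fold or more. The lower spot copy alone gave 123 higher and the upper copy alone 114 lower. Leaving out 1 array gave 66 to 184 higher and 40 to 203 lower. Fits on fewer arrays have fewer degrees of freedom; for the other settings the cause was not tested. The share of higher calls stayed within 46.0% to 49.8% under the other scalings and centrings, against 48.8%, but over 25 alternatives, the size threshold left aside, it ran from 46.0% to 86.0%, the highest under the replicate block without dye term. For the sigD plasmid, 52 rose and 7 fell by at least 2-fold, and leaving out 1 array gave 1017 to 1140 higher and 963 to 1124 lower. For the vector these were 13 and 3, with 751 to 938 and 645 to 916.

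The labels do not say whether equal replicate numbers pair the arrays. The correlations here cannot decide it, since they rest on deviations from means of few arrays with a fitted dye term removed. Deviations from the group means of same-numbered arrays correlated with r of -0.06 to 0.56, and 1 of 3 vector arrays correlated best with its own number. With the replicate number as a block, 66 and 30 probes differed with the dye term and 37 and 6 without it. Without the dye term 729 and 672 were called for sigD and 369 and 255 for the vector, and with it the vector had 571 lower.

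Slide as a block was not run, since each slide held 1 array, nor the median over probes, since each probe stood alone with 2 spots. The sigD probe, the gene lists and the promoter motif were not run for want of gene names. Signals over background limit the 136 probes that were left out as dim.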

Other observations

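Of the tests in this part, those of slide position and of neighbouring genes in one transcript were set before their results were seen, and that of random placement after. Probes that responded alike often carried consecutive numbers. Between consecutive numbers the rank correlation was 0.23 for the response with the sigD plasmid, 0.21 for that with the vector and 0.34 for their difference. The likeness was thus not particular to the difference, to which the runs below refer. Of the 201 probes higher with the sigD plasmid, 97 (48.3%) lay in 39 runs of at least 2 consecutive numbers, 12 of the runs had at least 3 probes and the longest had 7. Of the 211 lower probes, 74 (35.1%) lay in 27 runs, the longest with 8. ID_763 opened a run of 3 in which the difference was 3.12 to 6.28 on the log2 scale. ID_2154 lay in a run of 6 with differences of 0.21 to 3.52. The run of 7 had differences of 0.55 to 2.32, with vector responses of -0.09 to 0.34. ID_1275, which fell, ended a run of lower probes, and the next number opened a run of 3 higher probes with differences of 0.23 to 2.40.

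The run of 8 lower probes showed another form of difference. Its probes rose by 0.37 to 0.86 on the log2 scale with the vector and had responses of -0.24 to 0.22 with the sigD plasmid. The differences were -0.70 to -0.59.

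The runs call for an explanation. Called probes falling at random over the numbers is argued against by 58 adjacent pairs among the 201 higher probes, where 100000 random draws of tested probes gave 12.3 on average and 28 at most (permutation p = 1e-05, one-sided, the smallest these draws can give). The lower probes held 47 pairs against 13.6 on average and 30 at most, and the 33 probes at least 2-fold higher held 12 against 0.321 and 5. Neighbouring spots on the slide are argued against as well. Differences of consecutive numbers correlated with a rank correlation of 0.34 over 3022 pairs. Touching spots with distant numbers gave 0.04. Pairs at the same slide offsets with distant numbers gave 0.01. That value pools 173 offsets without weighting them by how often consecutive numbers had them. The most frequent offset, which 1354 of the consecutive pairs had, was not taken alone. That adjacent numbers stand for neighbouring genes read in one transcript may explain the runs, and it stays open as a hypothesis, because 0 tested probes have a gene name in the files.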
